A study of Mus musculus with 13 samples.

How the data were processed

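RNA sequencing measured total RNA in 13 libraries of common lymphoid progenitors (CLP), the bone marrow cells from which lymphocytes develop, taken from wild-type C57BL/6 mice. The cells were sorted by fluorescence-activated cell sorting on the surface proteins Ly6D and Gfra2 into 3 compartments, with 6 libraries of Ly6D−Gfra2− cells, 4 of Ly6D+Gfra2− cells and 3 of Ly6D+Gfra2+ cells. RNA was purified with a Qiagen RNeasy micro kit, and libraries were built with NuGEN Ovation RNA-Seq and Ovation Ultralow kits. The library names carry a prefix, P or T, whose meaning is not stated. Ly6D−Gfra2− replicates 1, 2 and 3 and Ly6D+Gfra2− replicates 1 and 2 have prefix P, and all other libraries, with all 3 Ly6D+Gfra2+ libraries among them, have prefix T.

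The deposited values are, per the file headers, raw counts per RefSeq identifier, with 1 file for each library. The authors' processing notes name FastQC, HISAT, TopHat, HOMER and DESeq and the mm10 genome build, without the role, version or order of any of them. The annotation version, the strand setting and the handling of reads that map to several places are not stated. Because the strand is not stated, reads of antisense or overlapping transcripts cannot be told from those of the gene itself. Every file held the same 24072 identifiers, of which 23815 were named from the RefSeq gene table for assembly GRCm38.p6, the assembly also called mm10, and 144 from GENCODE release M21. The remaining 113 had no name. Coordinates are those of the RefSeq gene table. The paralogs Hbb-b1 and Hbb-bs, and Vpreb1 and Vpreb2, share sequence, so counts may be shared between members of each pair.

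Counts were tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3. All 13 libraries entered 1 fit with a term for the group and a term for the prefix, with TMM normalization. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 12722 genes. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05. Levels are CPM, counts per 1000000 counts of the TMM-scaled library size, given as mean ± SD over the libraries of a group. Fold changes are given as log2 values with the standard error (SE) of the fit, first group minus second.

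Before the data were examined, the groups, the 3 comparisons, this test, the gene lists, the rule for named genes and a set of alternatives were fixed. The 16 gene lists held 310 genes and covered B lineage, V(D)J recombination, lymphoid signalling and priming, T lineage and Notch, NK and innate lymphoid, dendritic cell, granulocyte and monocyte, erythroid and megakaryocyte, stem cell and multipotent progenitor, mature B and plasma cell, stroma and endothelium, G2 and mitosis, G1/S and replication, Myc and ribosome biogenesis, immediate early and dissociation stress, and interferon response. Each list was tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Alternatives were camera with an estimated correlation and the rotation test fry. The rule named Ly6d and Gfra2. It then named, per comparison, up to 10 genes in each direction with the largest fold change among called genes. These needed a mean of at least 5 CPM in the higher group and no overlap of the groups within a prefix that holds both. It also named up to 4 members of each list with the smallest p, and described members of the B lineage, V(D)J, lymphoid signalling and T lineage lists. Some genes that the rule names are not reported here.

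A gene at 0 in all libraries of a group is given as a bound, computed against 3 counts over the group's libraries together. A gene with 1 to 3 counts in a group is given as a ratio with its 95% counting interval. These intervals and bounds cover counting error only, since reads copied by amplification are not separate molecules. The design was tested on simulated data, in which 100 genes per fold size were changed. The fit between Ly6D+Gfra2− and Ly6D−Gfra2− found 45% of genes changed 4-fold and 76% of those changed 16-fold. The other 2 comparisons found 16% and 59% (Ly6D+Gfra2+ against Ly6D+Gfra2−) and 27% and 66% (Ly6D+Gfra2+ against Ly6D−Gfra2−). False calls numbered 4 of 134, 0 of 82 and 4 of 107. The simulation drew each gene independently from the spread fitted to these libraries. It set no library apart from its group over many genes and held no library with few genes detected. The real libraries can therefore give other shares and more false calls.

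Alternatives fixed in advance were DESeq2 1.42.0, limma voom with quality weights, RLE size factors, library size alone, no filter on low counts, a filter of at least 5 CPM in 3 libraries, and a minimum log2 fold change of 1. Others were no prefix term, the replicate number in place of the prefix, only the 2 groups compared, only libraries of prefix T, only those of prefix P, and each library left out in turn. Alternatives chosen after seeing the data left out 3 libraries together (the library labelled Ly6D−Gfra2− replicate 3, Ly6D+Gfra2− replicate 1 and Ly6D+Gfra2+ replicate 5), used robust dispersions, or dropped the unnamed identifier NR_046233. Another kept prefix P without the library labelled Ly6D−Gfra2− replicate 3, and the gene lists were tested within prefix P, and with an estimated correlation with 1 library left out and within prefix T. No library was left out of the values reported first.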

Results

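The series compares 3 compartments of bone marrow CLP under a title on heterogeneity within early lymphoid compartments. Gene expression was measured by RNA sequencing in 6 libraries of Ly6D−Gfra2− cells, 4 of Ly6D+Gfra2− cells and 3 of Ly6D+Gfra2+ cells. Ly6D is a surface protein that appears on lymphoid progenitors as they turn toward the B lineage, and Gfra2 is a receptor subunit for the growth factor neurturin. Total counts in Ly6D−Gfra2− replicates 1 to 6 were 9841953, 23705975, 20384528, 7732049, 10847792 and 6892728. In Ly6D+Gfra2− replicates 1, 2, 5 and 6 they were 17838377, 20098978, 10285658 and 9200722, and in Ly6D+Gfra2+ replicates 4, 5 and 6 they were 9287598, 9771228 and 9400568. At these depths 3 counts in a library correspond to between 0.133 and 0.389 CPM. The labels do not say whether the replicates are separate animals, so the p-values measure only the spread between these libraries.

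The sort markers were read first, in every library. Ly6d (NM_010742, chromosome 15, 74762056 to 74763567) was at 158, 169, 349 and 507 CPM in the Ly6D+Gfra2− libraries and at 171, 283 and 205 CPM in the Ly6D+Gfra2+ libraries. In 5 of the 6 Ly6D−Gfra2− libraries Ly6d lay between 0.623 and 8.30 CPM. The library labelled Ly6D−Gfra2− replicate 3 had 213 CPM of Ly6d, inside the range of the Ly6D-positive libraries. Gfra2 (NM_008115, chromosome 14, 70890107 to 70979840) was at 287, 515 and 365 CPM in the Ly6D+Gfra2+ libraries, against at most 14.7 CPM in Ly6D+Gfra2− and 5.50 CPM in Ly6D−Gfra2−. The log2 fold change of Ly6d between Ly6D+Gfra2− and Ly6D−Gfra2− was 4.12 (SE 1.33; adjusted p = 0.807) with all libraries. Without the library labelled Ly6D−Gfra2− replicate 3 it was 5.91 (SE 0.52; adjusted p = 6.29e-05), and within prefix T it was 6.19 (adjusted p = 0.000127). Within prefix P, which holds that library, it was 1.15 (adjusted p = 0.917), and 5.52 (adjusted p = 0.993) when that library was left out there. Against Ly6D−Gfra2−, Ly6D+Gfra2+ had a log2 fold change of Ly6d of 4.01 (SE 1.58; adjusted p = 0.236), which became 5.10 (SE 0.56; adjusted p = 0.000161) without that library and 5.22 (adjusted p = 0.000108) within prefix T.

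**Figure D1:**
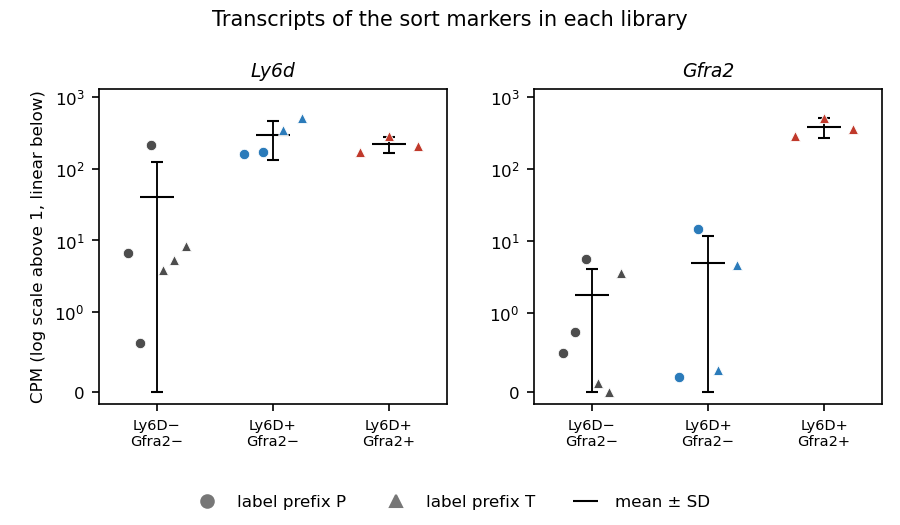
Ly6d and Gfra2 in each of the 13 libraries, in CPM on a log axis that is linear below 1, with circles for prefix P, triangles for prefix T and mean ± SD per group (bars end at 0 where the SD exceeds the mean). The library labelled Ly6D−Gfra2− replicate 3, at 213 CPM of Ly6d, lies among the Ly6D-positive libraries, and Gfra2 is at 287 to 515 CPM in the 3 Ly6D+Gfra2+ libraries.

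B-lineage genes were higher in Ly6D+Gfra2− than in Ly6D−Gfra2− cells, and genes of granulocytes, monocytes and stem cells were lower. The comparison asks which transcripts differ with Ly6D among cells without Gfra2. The 24 measured B-lineage genes rose as a group (adjusted p = 2.27e-09; adjusted p = 0.0352 with an estimated correlation), with a median log2 fold change of 1.25, and 17 of the 24 had positive values. Ebf1, the transcription factor that starts the B-cell programme (NM_001290711, chromosome 11, 44618100 to 45008096), was at 136.5 ± 33.6 CPM (SD, n = 4) in Ly6D+Gfra2− and 39.3 ± 44.6 CPM (SD, n = 6) in Ly6D−Gfra2−. Siglech, a receptor of plasmacytoid dendritic cells (NM_178706, chromosome 7, 55768154 to 55779448), was at 293 ± 51.0 CPM (n = 4) against 77.5 ± 109.9 CPM (n = 6).

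No single gene passed over all 12722 genes in this comparison with edgeR. The smallest adjusted p was 0.659, and 599 genes had an unadjusted p under 0.05. As a share of the 12722 genes this is below 0.05, no more than chance alone would give. DESeq2, run without the filter on 15193 genes, called 52 (25 up, 27 down) and gave no adjusted p for Ly6d. The 1 gene that limma voom called was Ly6d. Leaving out the library labelled Ly6D−Gfra2− replicate 3 raised the edgeR count from 0 to 16, all of them higher in Ly6D+Gfra2−. Attention fell on this library because of its own Ly6d level. In 14 of the 15 called genes other than Ly6d it was the highest of its label. Equal odds for each of the 6 libraries would give 2.5. The 15 genes were called without this library, however, which favours genes low in the other 5. The value of 2.5 is therefore too low for chance, and the count is not separate evidence. Small p-values in fits without this library, here and elsewhere, follow in part from leaving it out for its Ly6d level and are not separate evidence. Without that library Ebf1 had a log2 fold change of 2.89 (SE 0.32; adjusted p = 0.000719), at 136 ± 33.6 CPM (n = 4) against 21.7 ± 13.1 CPM (n = 5). Siglech then had 3.22 (SE 0.38; adjusted p = 0.000837), Rag1, a subunit of the V(D)J recombinase, 1.52 (SE 0.24; adjusted p = 0.0233), and Cd79a, part of the B-cell receptor, 3.83 (SE 0.66; adjusted p = 0.0325). Spib, Blk, Blnk and Foxo1 of the B-lineage list were also among the 16, with log2 fold changes of 7.07, 2.79, 1.26 and 1.42. Within prefix T (3 libraries against 2) edgeR called 1 gene, Ly6d, and the log2 fold changes were 2.32 for Ebf1 (adjusted p = 0.0679) and 3.72 for Siglech (adjusted p = 0.0679). Within prefix P the log2 fold changes were 1.37 for Ebf1 (adjusted p = 0.804) and 1.21 for Siglech (adjusted p = 0.773), and edgeR called 0 genes (838 of 12660 at an unadjusted p under 0.05). Within prefix P without the library labelled Ly6D−Gfra2− replicate 3 they were 3.54 and 2.59 (adjusted p = 0.937 for each). There edgeR again called 0 genes (553 of 12111 at an unadjusted p under 0.05, again a share below 0.05, smallest adjusted p 0.937). A test of whether the difference itself depended on the prefix called 0 genes with edgeR (872 of 12140 at an unadjusted p under 0.05, smallest adjusted p 0.592). Other tools were not run for it.

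Among the B-lineage genes, 0 of 24 passed over all genes and 7 passed when adjusted over the list alone, all 7 higher in Ly6D+Gfra2−. These were Cd79a (log2 fold change 3.19, SE 0.67), Blk (2.42, SE 0.54), Foxo1 (1.15, SE 0.29), Spib (4.93, SE 1.29), Ebf1 (1.86, SE 0.53), Blnk (0.94, SE 0.30) and Irf4 (2.15, SE 0.69). Pax5, which fixes B-cell identity, was at 0.327 ± 0.259 CPM (n = 4) and 1.16 ± 2.68 CPM (n = 6), with 6.62 CPM in the library labelled Ly6D−Gfra2− replicate 3 and at most 0.357 CPM in the other 5 of that label. Its log2 fold change was -0.86 (SE 1.71; adjusted p = 0.999) with all libraries and 2.55 (SE 1.02; adjusted p = 1) without that library. The 15 dendritic-cell genes rose as a group (adjusted p = 0.000179; adjusted p = 0.195 with an estimated correlation), and 3 passed when adjusted over the list alone, namely Siglech (2.57, SE 0.59), Irf8 (1.20, SE 0.35) and Runx2 (0.69, SE 0.23). Irf8 and Runx2 encode transcription factors used by plasmacytoid dendritic cells, and none of the 15 passed over all genes. Without the library labelled Ly6D−Gfra2− replicate 3 the adjusted p of the B-lineage list was 1.28e-20 (adjusted p = 8.38e-05 with an estimated correlation) and that of the dendritic list 4.45e-08 (adjusted p = 0.0122 with an estimated correlation).

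The 14 granulocyte and monocyte genes fell as a group (adjusted p = 2.12e-07; adjusted p = 0.0162 with an estimated correlation), with 0 passing over all genes and 3 adjusted over the list alone. Mpo, the peroxidase of neutrophil granules, had a log2 fold change of -0.96 (SE 0.31), and Lyz2, a lysozyme of myeloid cells, had -1.28 (SE 0.37). S100a9, a calcium-binding protein of neutrophils, was 1620 times higher in Ly6D−Gfra2− (95% counting interval 291 to 64200, against 1 count in the Ly6D+Gfra2− libraries together), and Ly6D−Gfra2− replicate 5 alone held 177 CPM of it. Without that library the ratio was 188 (33.5 to 7470). The 19 stem-cell and multipotent-progenitor genes fell as a group (adjusted p = 3.19e-05; adjusted p = 0.0352 with an estimated correlation), with 0 members passing either adjustment. Cd34 was at 253 ± 136 CPM (n = 4) against 453 ± 154 CPM (n = 6), and Kit, the receptor for stem cell factor, at 130 ± 30.9 CPM against 224 ± 64.9 CPM. The 15 erythroid and megakaryocyte genes fell (adjusted p = 0.000185; adjusted p = 0.228 with an estimated correlation), with 0 members passing either adjustment, a median of -2.44 and 14 negative values. Ly6D−Gfra2− replicate 5 held 141 CPM of Hbb-bs. The 20 G1/S and replication genes rose (adjusted p = 0.0184; adjusted p = 0.184 with an estimated correlation), with 0 members passing either adjustment and a median of 0.20. That call was lost without Ly6D+Gfra2− replicate 1 (adjusted p = 0.186), replicate 5 (adjusted p = 0.075) or replicate 6 (adjusted p = 0.0519), and with the replicate number in place of the prefix (adjusted p = 0.0559). With that term the Myc and ribosome biogenesis list passed, lower in Ly6D+Gfra2− (adjusted p = 0.022). Without the library labelled Ly6D−Gfra2− replicate 3 the Myc and ribosome biogenesis list also passed, lower in Ly6D+Gfra2− (adjusted p = 0.0358; adjusted p = 0.287 with an estimated correlation), and the immediate early list passed without Ly6D−Gfra2− replicate 6 (adjusted p = 0.0208, higher; adjusted p = 0.358 with an estimated correlation).

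Within prefix T all 6 lists passed in the same direction, with an adjusted p of 1.55e-16 for the B lineage, 2.55e-09 for dendritic-cell, 9.52e-06 for granulocyte and monocyte, 1.28e-06 for erythroid, 1.09e-05 for stem-cell and 0.0411 for G1/S genes, and the NK and innate lymphoid list passed as well (0.0322, higher). With an estimated correlation within prefix T the B-lineage (0.00345), dendritic (0.00867) and stem-cell (0.0207) lists passed, and the granulocyte and monocyte (0.0798), erythroid (0.139), G1/S (0.139) and NK (0.162) lists did not. Within prefix P the B-lineage list (adjusted p = 0.0101) and the granulocyte and monocyte list (0.000253) passed, whereas the dendritic (0.73), erythroid (0.109), stem-cell (0.109) and G1/S (0.591) lists did not. Within prefix P without the library labelled Ly6D−Gfra2− replicate 3 the adjusted p was 1.19e-06 for B-lineage, 4.02e-06 for granulocyte and monocyte, 0.0396 for dendritic-cell, 0.00504 for stem-cell, 0.692 for erythroid and 0.678 for G1/S genes.

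Ly6D+Gfra2+ cells had more transcripts of early B-cell genes than Ly6D+Gfra2− cells and less of Cd28 and Runx2. The comparison asks which transcripts differ with Gfra2 among Ly6D-positive cells. Rag1 (NM_009019, chromosome 2, 101638252 to 101649532) rose from 189 ± 30.8 CPM (n = 4) to 1309 ± 77.2 CPM (n = 3), a log2 fold change of 2.98 (SE 0.45; adjusted p = 0.00649). Pou2af1, a coactivator of octamer-binding factors in B cells (NM_011136, chromosome 9, 51213690 to 51240079), rose from 11.6 ± 22.3 CPM to 1037 ± 157 CPM (6.28, SE 1.19; adjusted p = 0.0336). Cd79a (NM_007655, chromosome 7, 24897497 to 24901858) rose from 4.36 ± 2.32 CPM to 153 ± 89.3 CPM (5.04, SE 0.84; adjusted p = 0.0159). Cd28, the T-cell costimulatory receptor (NM_007642, chromosome 1, 60746388 to 60773359), fell from 80.1 ± 37.1 CPM to 1.32 ± 0.814 CPM (-4.99, SE 0.67; adjusted p = 0.00384).

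In this comparison edgeR called 52 genes, 26 higher and 26 lower in Ly6D+Gfra2+, and 1677 genes had an unadjusted p under 0.05. The test used the shared fit of 13 libraries. DESeq2 called 714 genes (276 higher, 438 lower), 50 of the 52 among them, and limma voom called 25 (24 higher, 1 lower), 20 of the 52 among them. Normalized by library size alone edgeR called 48 (15 higher, 33 lower). The balance of directions thus differed between these settings, while all 52 kept their direction in them. DESeq2 was run without the filter and tested 15193 genes, so more than the tool changed there. Within prefix T (3 libraries against 2) edgeR called 9 genes (7 higher, 2 lower), of which 6 were among the 52. With only the 2 groups compared it called 8, of which 6 were among the 52, and with the replicate number in place of the prefix 25, of which 20 were. Rag1 (2.83, adjusted p = 0.00843) and Runx2 (-2.46, adjusted p = 0.00303) passed within prefix T, whereas Pou2af1 (5.48, adjusted p = 0.116), Cd79a (4.64, adjusted p = 0.0546) and Cd28 (-5.32, adjusted p = 0.0884) did not. The count moved by more than 1.5 times without any 1 of 11 libraries. It was 184 without Ly6D+Gfra2+ replicate 6, 94 without replicate 4 and 23 without replicate 5. It was 24, 12 and 17 without Ly6D+Gfra2− replicates 2, 5 and 6. It was 19, 18, 15, 15 and 17 without Ly6D−Gfra2− replicates 1, 2, 4, 5 and 6, which enter the shared estimate of the spread. Of the 25 called genes named by the rule and reported here, 5 were called whichever library was left out (Fry, Cd24a, Rag1, Cd28 and Runx2), and each of the others lost the call at least without Ly6D+Gfra2− replicate 5. All 25 kept their direction, which was nearly fixed in advance, since called genes were refitted on most of the same libraries.

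Among the genes with the largest increases, Igll1, a component of the surrogate light chain of the pre-B-cell receptor (NM_001190325, chromosome 16, 16860671 to 16863985), was at 109.5 ± 50.3 CPM (n = 3) in Ly6D+Gfra2+. The ratio to Ly6D+Gfra2−, which held 1 count, was 6010 (95% counting interval 1080 to 237000; adjusted p = 0.0314). Gfra2 itself rose with a log2 fold change of 7.14 (SE 1.43; adjusted p = 0.0428), against 7.32 (adjusted p = 0.139) within prefix T and 6.65 (adjusted p = 0.0759) without the library labelled Ly6D−Gfra2− replicate 3. Its call was also lost without Ly6D−Gfra2− replicate 1 (adjusted p = 0.057), 2 (0.0531), 4 (0.0772) or 5 (0.0609), without Ly6D+Gfra2− replicate 5 (0.128) or 6 (0.116), and without Ly6D+Gfra2+ replicate 5 (0.0634). Cecr2, a chromatin-remodelling factor, rose by 4.42 (SE 0.86), the GTPase gene Gimap4 by 4.03 (SE 0.74), the adaptor gene Gab1 by 3.37 (SE 0.63), Chchd10 by 3.63, Gpr89 by 3.41 and Pced1b by 3.13. The largest decreases were of genes at or near 0 in Ly6D+Gfra2+. Strip2 was at least 328-fold lower, Acot11 at least 126-fold, S100a13 at least 122-fold, Cttn at least 113-fold, Ebi3 at least 81.4-fold, Clu at least 73.9-fold and Epha7 at least 50.4-fold. Fry and Spring1, each with 1 count in Ly6D+Gfra2+, were lower by a ratio of 956 (171 to 37800) and 1120 (200 to 44100). The ratio of Spring1 was 165 (29.4 to 6560) without Ly6D+Gfra2− replicate 1 and 1690 (303 to 66800) without replicate 2. The Ly6D+Gfra2+ libraries had some of the lowest numbers of genes with at least 1 count, at 11873, 10837 and 12369, beside 11636 in Ly6D+Gfra2− replicate 1 and 12904 to 13969 in the other libraries. Of 10334 genes with a mean of at least 5 CPM in Ly6D−Gfra2−, 43 were at 0 in all 3 Ly6D+Gfra2+ libraries. In the 6 sets of 3 libraries drawn from both groups with a total of zeros within 10% of that group's, 11 to 31 were at 0 in all 3, and the most in any of the 30 mixed sets was 44.

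The 24 B-lineage genes rose as a group (adjusted p = 1.12e-15; adjusted p = 0.0336 with an estimated correlation), with 5 higher over all genes. Adjusted over the list alone, 14 were higher and 1, Spib, was lower. The 5 were Igll1, Pou2af1, Cd79a, Cd24a, a surface protein of B-cell precursors (1.87, SE 0.27; adjusted p = 0.00424), and Foxo1, a transcription factor acting upstream of the Rag genes (1.82, SE 0.38; adjusted p = 0.0471). Ebf1 was at 840.4 ± 75.4 CPM (n = 3) against 136.5 ± 33.6 CPM (n = 4), with a log2 fold change of 2.80 (SE 0.68; adjusted p = 0.0814). It passed without the library labelled Ly6D−Gfra2− replicate 3 (2.18, SE 0.40; adjusted p = 0.0269) and within prefix T (2.54, adjusted p = 0.0365). Pax5 was at 81.8 ± 24.7 CPM (n = 3) against 0.327 ± 0.259 CPM (8.63, SE 1.89; adjusted p = 0.0569). The 15 dendritic-cell genes fell as a group (adjusted p = 1.14e-06; adjusted p = 0.152 with an estimated correlation), with 1 lower over all genes and 7 adjusted over the list alone. Runx2 (NM_001145920, chromosome 17, 44495987 to 44814797) fell from 1782 ± 290 CPM to 348 ± 71.6 CPM (-2.17, SE 0.30; adjusted p = 0.00384), and Siglech was at 18.4 ± 10.4 CPM against 293 ± 51.0 CPM (-3.33, SE 0.74; adjusted p = 0.0606). Irf8 was at 180.1 ± 85.9 CPM against 759 ± 137 CPM (-1.70, SE 0.43; adjusted p = 0.0986). The 20 Myc and ribosome biogenesis genes rose as a group (adjusted p = 0.000619; adjusted p = 0.152 with an estimated correlation), with 1 higher over all genes, Pprc1 (1.80, SE 0.34; adjusted p = 0.0336), and 5 adjusted over the list alone.

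Other lists did not pass in camera in this comparison with all libraries, and 3 of them passed when 1 library was left out. The V(D)J recombination list (adjusted p = 0.0689) passed, higher in Ly6D+Gfra2+, without Ly6D−Gfra2− replicate 2 (adjusted p = 0.0425), without the library labelled Ly6D−Gfra2− replicate 3 (adjusted p = 0.0301), without Ly6D+Gfra2+ replicate 5 (adjusted p = 0.0298) and within prefix T (adjusted p = 0.0143). Its 12 genes had a median log2 fold change of 0.04 with all libraries. Rag1 was the 1 called over all genes, and 2 passed adjusted over the list alone. The T lineage and Notch list (adjusted p = 0.0689) passed, lower in Ly6D+Gfra2+, without Ly6D+Gfra2− replicate 1 (adjusted p = 0.0276), without Ly6D−Gfra2− replicate 4 (adjusted p = 0.047) and within prefix T (adjusted p = 0.0299). Cd28 was the 1 of its 14 measured genes called over all genes, and adjusted over the list alone 1 was higher and 3 were lower. The NK and innate lymphoid list (adjusted p = 0.0555) passed, lower, without Ly6D−Gfra2− replicate 2 (adjusted p = 0.0425), replicate 4 (adjusted p = 0.047), replicate 5 (adjusted p = 0.0419) or the library labelled replicate 3 (adjusted p = 0.0301). It also passed without Ly6D+Gfra2− replicate 1 (adjusted p = 0.0271), without Ly6D+Gfra2+ replicate 6 (adjusted p = 0.0342), within prefix T (adjusted p = 0.0116) and with the replicate number in place of the prefix (adjusted p = 0.0326; an estimated correlation was not run with that term). With an estimated correlation none of the other calls of the 3 lists held, the adjusted p in the same settings being 0.135 to 0.219 for V(D)J recombination, 0.0962 to 0.172 for T lineage and Notch and 0.0962 to 0.264 for NK and innate lymphoid genes. The lymphoid signalling and priming list did not pass (adjusted p = 0.105), and Il7r, the receptor for interleukin 7, was at 926 ± 185 CPM (n = 3) against 665 ± 89.9 CPM (n = 4). Within prefix T the adjusted p was 8.57e-21 for the B-lineage list, 6.78e-10 for the dendritic list and 0.00172 for the Myc and ribosome biogenesis list, with the direction of the pooled values (0.00197, 0.00864 and 0.219 with an estimated correlation).

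**Figure D2:**
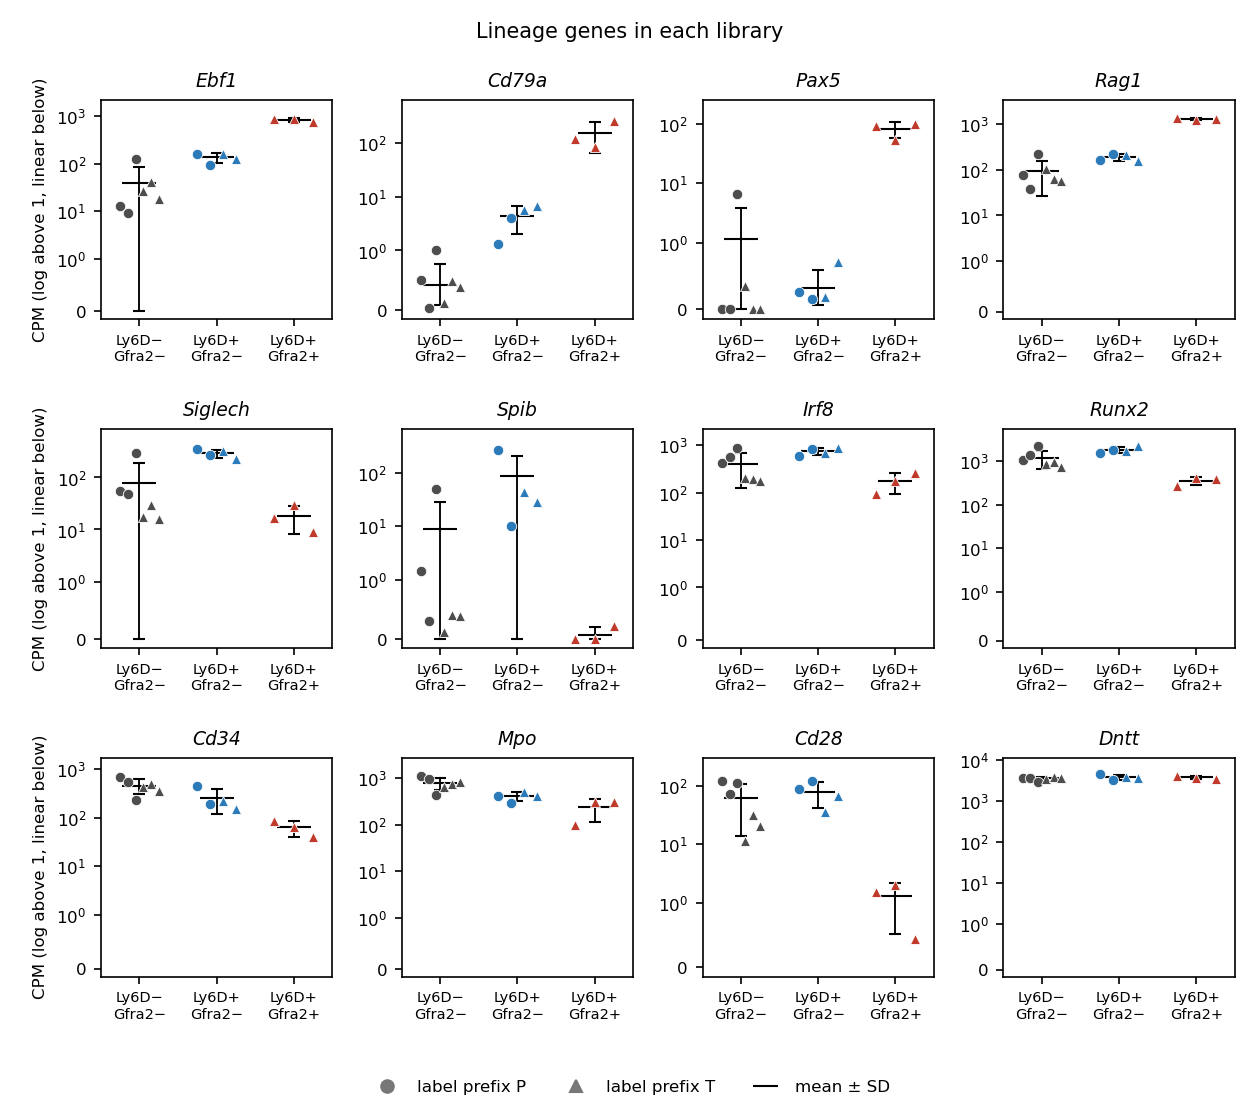
Expression of 12 genes in each of the 13 libraries, in CPM on a log axis that is linear below 1, with circles for prefix P, triangles for prefix T and mean ± SD per group (bars end at 0 where the SD exceeds the mean). Ebf1, Rag1, Cd79a and Pax5 have their highest mean in Ly6D+Gfra2+ cells, Siglech, Irf8 and Runx2 in Ly6D+Gfra2− cells and Cd34 and Mpo in Ly6D−Gfra2− cells, while Dntt has means of 3479, 3749 and 3694 CPM.

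Between the ends of the series, Ly6D+Gfra2+ cells had more B-lineage, Rag and Il7r transcripts than Ly6D−Gfra2− cells and less of Cd34 and Mpo. Ebf1 rose from 39.3 ± 44.6 CPM (n = 6) to 840.4 ± 75.4 CPM (n = 3), a log2 fold change of 4.66 (SE 0.69; adjusted p = 0.00325) and of 4.86 within prefix T (adjusted p = 7.6e-05). Rag1 rose from 93.4 ± 66.8 CPM to 1309 ± 77.2 CPM (4.03, SE 0.44; adjusted p = 0.000166; 4.13 within prefix T, adjusted p = 7.6e-05), and Cd79a from 0.428 ± 0.348 CPM to 153 ± 89.3 CPM (8.23, SE 0.91; adjusted p = 0.000166; 8.74 within prefix T, adjusted p = 0.00031). Cd34, a surface protein of stem and progenitor cells (NM_001111059, chromosome 1, 194938821 to 194961292), fell from 453 ± 154 CPM to 63.1 ± 23.4 CPM (-2.62, SE 0.41; adjusted p = 0.00388; -2.75 within prefix T, adjusted p = 0.00296). Mpo (NM_010824, chromosome 11, 87793784 to 87804412) fell from 792 ± 242 CPM to 239.5 ± 123 CPM (-1.75, SE 0.38; adjusted p = 0.0325; -1.64 within prefix T, adjusted p = 0.0994).

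In this comparison edgeR called 177 genes, 118 higher and 59 lower in Ly6D+Gfra2+, and 1953 genes had an unadjusted p under 0.05. DESeq2 called 946 genes (382 higher, 564 lower), 175 of the 177 among them, and limma voom called 109 (105 higher, 4 lower), 89 of the 177 among them. Normalized by library size alone edgeR called 111 (45 higher, 66 lower). Here too the balance of directions differed between these settings, while all 177 kept their direction in them. DESeq2 again tested 15193 genes without the filter. Within prefix T (3 libraries against 3) edgeR called 62 genes (54 higher, 8 lower), 54 of them among the 177. With only the 2 groups compared it called 72, 67 of them among the 177, and with the replicate number in place of the prefix 92, 85 of them among the 177. The count moved by more than 1.5 times without any 1 of 7 libraries. It was 90, 55, 49 and 52 without Ly6D−Gfra2− replicates 1, 4, 5 and 6, 106 without Ly6D+Gfra2− replicate 6, and 115 and 372 without Ly6D+Gfra2+ replicates 5 and 6. Of the 38 called genes named by the rule and reported here, 17 were called whichever library was left out, and the others lost the call without at least 1 of Ly6D−Gfra2− replicates 4, 5 and 6. All 38 kept their direction, which was nearly fixed in advance, since called genes were refitted on most of the same libraries.

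Further genes with large increases included Pou2af1 (8.46, SE 1.53; adjusted p = 0.0126), Igll1 (8.14, SE 1.26; adjusted p = 0.00881), Vpreb1, the other surrogate light chain gene (7.42, SE 1.76; adjusted p = 0.047), Cecr2 (6.78, SE 0.92), Chchd10 (5.54, SE 0.80) and Pde2a, a cyclic nucleotide phosphodiesterase (4.91, SE 0.54; adjusted p = 0.000166). Gfra2 rose by 8.57 (SE 1.32; adjusted p = 0.00388). Dlg2, a scaffold protein gene, was higher by a ratio of 1180 (95% counting interval 327 to 9800, against 2 counts in Ly6D−Gfra2−). Of the 177 genes, 13 were at 0 in all libraries of a group. Ddx4 was at least 183-fold lower in Ly6D+Gfra2+, Acot11 at least 117-fold, Epha7 at least 114-fold, Ebi3 at least 111-fold, Naip6 at least 91.9-fold, Tmem86a at least 66.8-fold, Clu at least 63.5-fold and Ppic at least 46.0-fold. Fry was lower by a ratio of 681 (122 to 26900, against 1 count). These genes belong to a group with few genes detected, where 43 of 10334 genes with a mean of at least 5 CPM in Ly6D−Gfra2− were at 0 in all 3 libraries.

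The 24 B-lineage genes rose as a group (adjusted p = 1.91e-29; adjusted p = 0.00267 with an estimated correlation), with a median log2 fold change of 3.60. Of these 10 rose over all genes, and 19 adjusted over the list alone. Besides those named, the 10 held Foxo1 (2.97, SE 0.36), Blnk, an adaptor of B-cell receptor signalling (2.37, SE 0.38), Blk (3.46, SE 0.68), Irf4 (from 5.18 ± 4.54 to 85.3 ± 21.9 CPM; adjusted p = 0.0336) and Cd24a (1.87, SE 0.25). Pax5 had a log2 fold change of 7.77 (SE 1.98; adjusted p = 0.0643), which became 9.74 (SE 1.16; adjusted p = 0.000313) without the library labelled Ly6D−Gfra2− replicate 3. The V(D)J recombination list passed as higher (adjusted p = 0.0189; adjusted p = 0.0902 with an estimated correlation), though its 12 genes had a median log2 fold change of 0.09, with 7 positive and 5 negative values. The 2 that passed, over all genes and adjusted over the list alone, were Rag1 and Rag2 (1.19, SE 0.28; adjusted p = 0.0446). That list lost its call without Ly6D+Gfra2+ replicate 4 (adjusted p = 0.138) or replicate 6 (adjusted p = 0.0534). Dntt, the enzyme that adds bases at V(D)J joints, had a log2 fold change of 0.07 (SE 0.13). The lymphoid signalling and priming list passed as higher (adjusted p = 0.0246; adjusted p = 0.0902 with an estimated correlation), though its 20 genes had a median log2 fold change of 0.05, with 13 positive and 7 negative values, and 3 passed over all genes and adjusted over the list alone. They were Il7r (1.19, SE 0.24; adjusted p = 0.0228), Myb (0.82, SE 0.17; adjusted p = 0.0231) and Foxp1 (0.64, SE 0.15; adjusted p = 0.0477). The list lost its call without Ly6D−Gfra2− replicate 4 (adjusted p = 0.0647) and without Ly6D+Gfra2+ replicate 5 (adjusted p = 0.0561) or replicate 6 (adjusted p = 0.113).

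The 19 stem-cell and multipotent-progenitor genes fell as a group (adjusted p = 0.00187; adjusted p = 0.0902 with an estimated correlation), with 2 lower over all genes, Cd34 and Lmo2 (-1.77, SE 0.38; adjusted p = 0.0305), and 5 adjusted over the list alone. The 14 granulocyte and monocyte genes fell (adjusted p = 0.00378; adjusted p = 0.0902 with an estimated correlation), with 3 lower over all genes and 5 adjusted over the list alone. The 3 were Mpo, Itgam, an integrin of myeloid cells (-2.87, SE 0.54; adjusted p = 0.0157), and S100a9, lower by a ratio of 768 (138 to 30300, against 1 count; adjusted p = 0.0417). Without Ly6D−Gfra2− replicate 5, which held 177 CPM of S100a9, its ratio was 89.0 (15.8 to 3530) and the call was lost (adjusted p = 0.257). The 15 dendritic-cell genes fell (adjusted p = 0.00821; adjusted p = 0.275 with an estimated correlation), with Runx2 lower over all genes (-1.48, SE 0.29; adjusted p = 0.0204) and 5 lower adjusted over the list alone. The call of the dendritic list was lost without Ly6D+Gfra2+ replicate 6 (adjusted p = 0.113) and within prefix T (adjusted p = 0.0545). The 20 Myc and ribosome biogenesis genes rose (adjusted p = 0.0154; adjusted p = 0.251 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone and 16 positive values, and this call was lost without Ly6D+Gfra2+ replicate 6 (adjusted p = 0.113). The T lineage and Notch list did not pass in camera (adjusted p = 0.0939) but did with fry (adjusted p = 0.00646, lower). Cd28 (-4.28, SE 0.65; adjusted p = 0.00388) and Tcf7, a Notch target in early T cells (a ratio of 252, 45.1 to 9960, against 1 count), fell among its 14 measured genes. Adjusted over that list alone 1 was higher and 2 were lower. The NK and innate lymphoid list did not pass in camera (adjusted p = 0.108) but did with fry (adjusted p = 0.027, lower). Nfil3, a transcription factor of innate lymphoid cells, fell from 33.3 ± 28.7 CPM to 0.181 ± 0.313 CPM (adjusted p = 0.0167). The immediate early list did not pass (adjusted p = 0.0939) but did without Ly6D+Gfra2+ replicate 4 (adjusted p = 0.0278; adjusted p = 0.349 with an estimated correlation) or Ly6D−Gfra2− replicate 6 (adjusted p = 0.0242; adjusted p = 0.269 with an estimated correlation), higher in Ly6D+Gfra2+. Within prefix T the adjusted p was 1.34e-46 for the B-lineage list, 0.0116 for V(D)J recombination, 0.0116 for lymphoid signalling and priming, 0.000127 for stem-cell, 0.000938 for granulocyte and monocyte and 0.0326 for Myc and ribosome biogenesis genes, with the direction of the pooled values. With an estimated correlation within prefix T the B-lineage (0.000263) and stem-cell (0.0423) lists passed, and the other 4 had an adjusted p of 0.132 to 0.421.

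**Figure D3:**
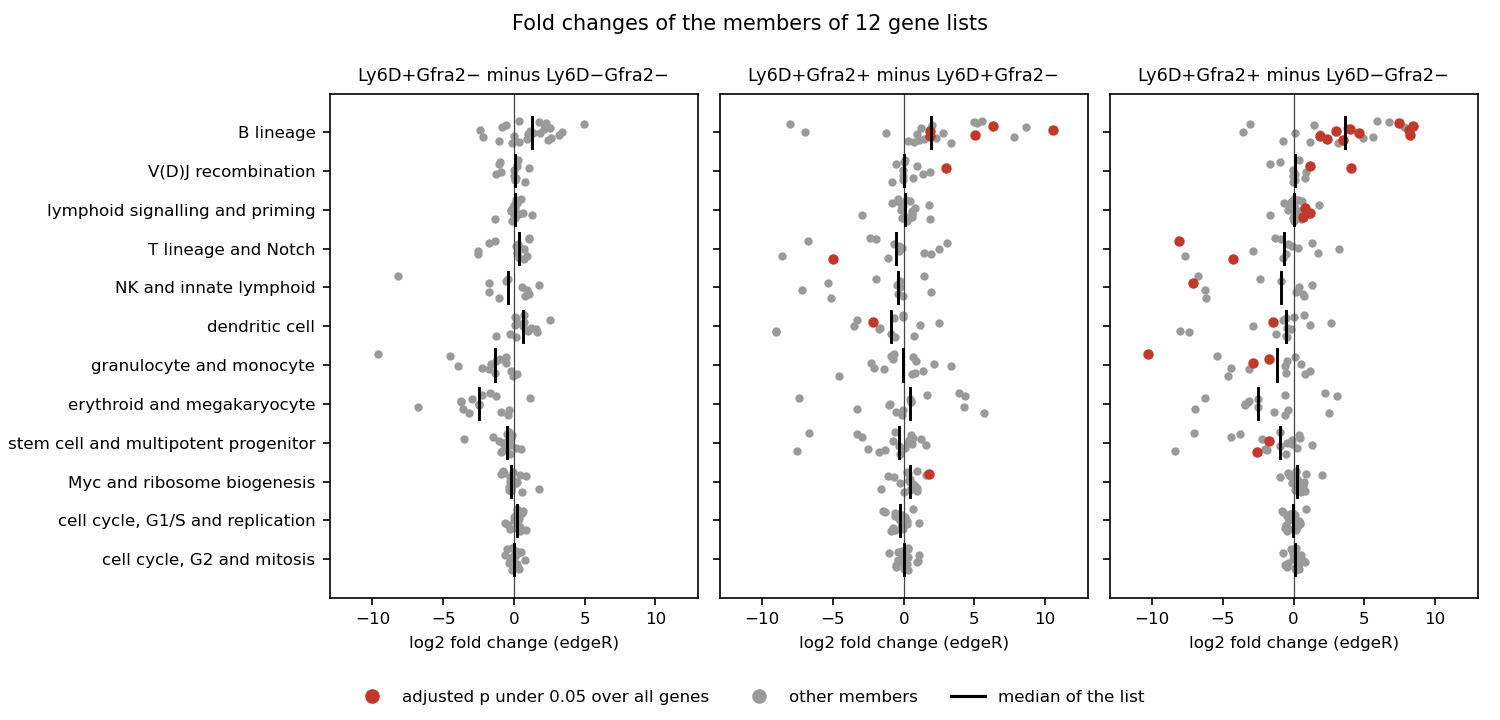
Log2 fold change of each measured gene of 12 gene lists in the 3 comparisons, with red for genes at an adjusted p under 0.05 over all genes and a black bar at the median of the list. The B-lineage medians are 1.25, 1.93 and 3.60 in Ly6D+Gfra2− against Ly6D−Gfra2−, Ly6D+Gfra2+ against Ly6D+Gfra2− and Ly6D+Gfra2+ against Ly6D−Gfra2−.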

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

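The tests of the library labelled Ly6D−Gfra2− replicate 3, of the label prefix and of the genes lower in Ly6D+Gfra2+ were chosen only after the results were seen, whereas the counts over other splits of the libraries were chosen before, except for those kept within prefix T.

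The library labelled Ly6D−Gfra2− replicate 3 held 213 CPM of Ly6d, where the other 5 libraries of its label held 0.623 to 8.30 CPM. It also stood apart from its group in Spib (49.8 CPM, others 0.119 to 1.49 CPM) and in Ccne2 (39.3 CPM, others 20.8 to 25.6 CPM). A swap with a Ly6D+Gfra2− library would need a partner low in Ly6d, and 0 of the 4 had such a level. Of 200 genes chosen without this library and without Ly6d, 116 were nearer the Ly6D+Gfra2− level than that of its label, against 43 to 75 in the other 5 libraries of the label when each was held out, which argues against a difference in Ly6d alone. Over 200 genes chosen in this way, the library lay at position 0.532 between the groups, inside the range of held-out Ly6D+Gfra2− libraries (0.473 to 0.671) and outside that of the other Ly6D−Gfra2− libraries (0.203 to 0.382), which is consistent with cells of the Ly6D+Gfra2− kind in this library. Pax5 went the other way, since its level in this library, given above, was far over that of the Ly6D+Gfra2− libraries. A wrong label and a sort that took in cells of the Ly6D+Gfra2− kind were not separated, and a difference between animals stays open and untested.

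All 3 Ly6D+Gfra2+ libraries have prefix T, so a difference between the prefixes could have entered the comparison with Ly6D−Gfra2−. With no prefix term 258 genes were called there, and within prefix T the median share of the log2 fold change that was left was 0.96 (quartiles 0.88 and 1.06), with the same direction in 258 of 258. A gene that followed the prefix alone would split the Ly6D−Gfra2− libraries and tend not to be called. The call also used the same libraries of prefix T, so this outcome was nearly fixed in advance. It shows only that the fold changes of these 258 genes were present within prefix T. The Y-linked genes Kdm5d, Ddx3y, Eif2s3y and Uty were at 0 in every library of prefix P and at 14.3 to 155 CPM in those of prefix T. The prefixes thus differ in the presence of male cells, which cannot be told apart from other differences between them. Xist, the transcript that silences an X chromosome, was at 10290 to 23040 CPM in prefix P and at 3100 to 11840 CPM in prefix T. Each library of prefix T thus held Xist and Y-linked transcripts together, which argues against cells of a single animal in it. What else the prefix stands for is not stated, and no biological explanation of it was tested.

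Several genes lower in Ly6D+Gfra2+ were at 0 there, in libraries with few genes detected. Of the 59 genes that fell against Ly6D−Gfra2−, 12 had a mean of at least 100 CPM in Ly6D−Gfra2− and 25 a mean under 20 CPM. At 100 CPM or more, 1 of 2210 tested genes was at 0 in any Ly6D+Gfra2+ library. This argues against genes going undetected as the whole source of the decreases. A partial loss that lowers a level without reaching 0 was not tested and stays open. Of 10334 genes, 43 were at 0 in all 3 Ly6D+Gfra2+ libraries, where losses at random and independent between libraries, at a rate set by the level of the gene, would give 7.1, and the highest of 1000 shuffles gave 15. This argues against such losses as the whole source of the 43. Mixed sets of 3 libraries from Ly6D+Gfra2− and Ly6D+Gfra2+ with a total of zeros within 10% of the group's also had more shared zeros than expected, by 3.6 to 8.0 times, against 6.1 times in the group. Losses that depend on the gene beyond its level, in libraries of both groups alike, therefore stay open, as does lower expression in Ly6D-positive cells, since every mixed set holds Ly6D+Gfra2+ libraries.

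Other splits of the same libraries were counted for each comparison. Between Ly6D+Gfra2− and Ly6D−Gfra2− the real split called 0 genes and the highest of the others called 4. With 0 genes in the real split, all 100 of the 100 splits drawn had to call at least as many, so this count says nothing about chance. Between Ly6D+Gfra2+ and Ly6D+Gfra2− 1 of 35 splits, the real one, called as many as 52 genes, and the highest other called 3. That share is under 0.05 only over splits that cross the prefixes. Every other split mixes libraries of both groups, which widens its spread and lowers its count, so chance is not excluded. The 10 splits that keep the first group within prefix T, as the real one does, are too few for a share under 0.05 (highest other 0), and the count within prefix T was 9. Between Ly6D+Gfra2+ and Ly6D−Gfra2− 1 of 84 splits, the real one, called as many as 177 genes. The highest other called 18 and set Ly6D−Gfra2− replicates 4, 5 and 6, its libraries of prefix T, apart from the rest. Here too the share is under 0.05 only over splits that cross the prefixes, and every other split mixes both groups, so chance is not excluded. The 20 splits that keep the first group within prefix T are too few for a share under 0.05 (highest other 18), and the count within prefix T was 62.

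Of 165 measures tested within a group, 9 had a library far from the others, where chance would give about 8.2. The remaining ones are values without an explanation. Igll1 was at 0.992 CPM in Ly6D−Gfra2− replicate 5 (others 0 to 0.119 CPM). Gpr89 was at 4.15 CPM in Ly6D−Gfra2− replicate 6 (others 14.2 to 27.4 CPM). In Ly6D+Gfra2− replicate 5, Igll1 was at 0.0933 CPM, with 0 in the other 3 libraries of the group. In Ly6D+Gfra2− replicate 6, S100a9 was at 0.101 CPM, with 0 in the other 3. Also in that replicate, Cecr2 was at 16.3 CPM (others 43.1 to 46.8 CPM) and Epha7 at 1.12 CPM (others 6.63 to 7.99 CPM). After thinning each library to 6892728 counts, Ly6D+Gfra2− replicate 1 had 11355 genes detected (others 12805 to 13029).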

How the results depend on the processing

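Leaving out 3 libraries together, robust dispersions, dropping NR_046233 and the tests within prefix P that leave out the library labelled Ly6D−Gfra2− replicate 3 or test lists, and the estimated correlation with 1 library left out or within prefix T, were chosen after seeing the data, and the other alternatives before. No result turned its direction past the threshold. Values are in the order Ly6D+Gfra2− against Ly6D−Gfra2−, Ly6D+Gfra2+ against Ly6D+Gfra2−, and Ly6D+Gfra2+ against Ly6D−Gfra2−, where the edgeR counts were 0 (599 at an unadjusted p under 0.05), 52 and 177. They were 52, 714 and 946 with DESeq2, 1, 25 and 109 with limma voom, 9, 164 and 318 with no filter, 8, 25 and 92 with a replicate block (the replicate number in place of the prefix), and 1, 9 and 62 within prefix T. The other counts that moved by more than 1.5 times were 8 and 72 with only the 2 groups compared (last 2 comparisons), 103 without the prefix term (middle comparison), 111 with library size alone (last comparison) and 23 without 3 libraries together (first comparison). Leaving out 1 library gave 0 to 16, 12 to 184 and 49 to 372. The cause was not tested, except that subsets hold fewer libraries, and that the number 3 is held by 1 library, so a term for the number removes the library labelled Ly6D−Gfra2− replicate 3. Of the genes called with all libraries, 52 of 52 and 177 of 177 kept their direction under RLE factors and under library size alone. Library size alone moved the median log2 fold change of all genes to -0.15 and -0.25, from 0.03 and 0.01. The single exception under the other settings was 1 gene without the prefix term (176 of 177). With 52 and 165 of the called genes at a log2 fold change of at least 1 in size, shifts of the medians like these could hardly turn a direction. Keeping direction under these 2 normalizations was thus nearly fixed in advance.

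Lists passing in camera numbered 6, 3 and 7. With an estimated correlation they numbered 3, 1 and 1, and with fry, which does not compare a list with other genes, 2, 5 and 9, with the B-lineage list of the first comparison at an adjusted p of 0.0528. With fry its dendritic (0.207), erythroid (0.21) and G1/S (0.136) lists did not pass either, nor did the Myc list of the last comparison (0.0654). The T lineage and Notch (0.019) and NK (0.0291) lists of the middle comparison passed with fry, both lower. So did the T lineage and Notch (0.00646), NK (0.027) and interferon response (0.027) lists of the last one, all lower. They numbered 6 within prefix T (middle comparison) and 2 within prefix P (first comparison). Leaving out 1 library gave 5 to 7, 3 to 5 and 3 to 8. With the replicate block the G1/S list of the first comparison did not pass (adjusted p = 0.0559), while its Myc list (0.022, lower) and the NK list of the middle one (0.0326, lower) did. Without the prefix term the lymphoid signalling (adjusted p = 0.057) and Myc (0.0844) lists of the last comparison did not pass, while its immediate early (1.38e-05) and erythroid (0.0237) lists and the immediate early list of the middle one (0.000846) did. In camera the immediate early list was higher in prefix T (adjusted p = 9.42e-36). The erythroid (0.0116) and Myc (0.0381) lists were lower there. All Ly6D+Gfra2+ libraries have prefix T, so without the term these differences enter both comparisons, in the direction of the changes seen. With an estimated correlation only the immediate early list differed between prefixes (0.00283). The lymphoid signalling list did not pass between them (0.58). Causes of the other changes were not tested.

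The Ly6d log2 fold change in the first comparison, 4.12, passed at 4.74 with limma voom, 6.08 with the replicate number as a term, 6.19 within prefix T and 5.99 without 3 libraries together, and lay between 3.40 and 5.91 when 1 library was left out, 5.91 being without the library labelled Ly6D−Gfra2− replicate 3. In the last comparison, 4.01, it passed at 3.83 with limma voom, 4.0 with no filter, 5.31 with the replicate number as a term, 5.22 within prefix T and 4.92 without 3 libraries together (3.20 to 5.10 without 1 library). Gfra2 in the middle comparison, 7.14, did not pass with only the 2 groups compared (7.33, adjusted p = 0.318), within prefix T (7.32, 0.139) or without 3 libraries together (6.22, 0.0579), and lay between 6.54 and 7.95 without 1 library, where it passed in 5 of 13 fits, its adjusted p being 0.0278 to 0.318 over the settings just named and 2.27e-05 with no filter. In the last comparison Gfra2 lay between 7.81 and 10.28 without 1 library, and at 7.77 without the prefix term. The cause was not tested. For genes named by the rule and reported here, alternatives with all or part of the libraries gave 1481 values on the same side of the threshold, 97 that passed only there, 161 that passed only with all libraries and 11 of uncalled genes with another sign, and leaving out 1 library gave 1373, 29, 277 and 11. Depth sets the limit for genes near 0, since 3 counts are up to 0.389 CPM.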

Other observations

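The comparison between prefixes in the fit of all libraries was looked at only after the data were seen. Between prefixes T and P, with the groups held in the model, 25 genes differed in edgeR at an adjusted p under 0.05. The Y-linked genes Kdm5d, Ddx3y, Eif2s3y and Uty were at 0 in all 5 libraries of prefix P and at 14.3 to 155 CPM in the 8 of prefix T, while Xist, the transcript that silences an X chromosome, was present in all 13. The 20 genes of the immediate early and dissociation stress list, which respond within minutes to stimulation or handling, were higher in prefix T as a group (adjusted p = 9.42e-36; adjusted p = 0.00283 with an estimated correlation), with positive values in all 20 and a median log2 fold change of 2.17. Of these 7 passed over all genes, among them Egr1 (3.43), Fosb (3.15), Dusp1 (2.77), Zfp36 (2.31) and Jun (1.54). With the preset correlation the erythroid (adjusted p = 0.0116), G1/S (0.0246) and Myc (0.0381) lists were lower in prefix T and the G2 and mitosis list (0.0181) was higher, and with an estimated correlation these 4 did not pass (0.326 to 0.512). Outside the lists, Dusp2 was higher by 2.25. Socs3 was higher by 2.93, while Lars2 (-1.32) and Pgr (-2.13) were lower. The unnamed identifier NR_046233 took 9.13% to 11.6% of the counts in prefix P and 2.07% to 7.44% in prefix T. Within prefix T its share also differed with the group. It was 6.35%, 7.44% and 4.40% in Ly6D+Gfra2+, 4.86% and 3.37% in Ly6D+Gfra2−, and 3.75%, 2.65% and 2.07% in Ly6D−Gfra2−. These genes were chosen after their values were seen.

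Ly6D−Gfra2− replicate 5 held 177 CPM of S100a9 and 87.4 CPM of S100a8, proteins of neutrophils, and 141 CPM of Hbb-bs and 86.1 CPM of Hba-a1, globins of red cells.

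Without the library labelled Ly6D−Gfra2− replicate 3, 16 genes were higher in Ly6D+Gfra2− than in Ly6D−Gfra2−, and 7 of them lay outside the rule for named genes there and were chosen after their values were seen. They were Lynx1 (log2 fold change 3.94, SE 0.65), Cecr2 (3.58, SE 0.41), Stum (2.77, SE 0.39), Tex2 (1.43, SE 0.25), Ly6e (1.15, SE 0.21), Tfrc, the transferrin receptor (1.14, SE 0.20), and Fryl (0.87, SE 0.15). Tfrc was at 885 ± 129 CPM (SD, n = 4) against 403 ± 69.0 CPM (SD, n = 5).

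Many gene lists did not pass in camera. In Ly6D+Gfra2− against Ly6D−Gfra2− the adjusted p was 0.45 for V(D)J recombination, 0.424 for lymphoid signalling and priming, 0.752 for T lineage and Notch, 0.765 for NK and innate lymphoid, 0.877 for mature B and plasma cell, 0.666 for stroma and endothelium, 0.794 for G2 and mitosis, 0.189 for Myc and ribosome biogenesis, 0.189 for immediate early and 0.269 for interferon response. For Ly6D+Gfra2+ against Ly6D+Gfra2− it was 0.838 for granulocyte and monocyte, 0.598 for erythroid and megakaryocyte, 0.427 for stem cell and multipotent progenitor, 0.698 for mature B and plasma cell, 0.786 for stroma and endothelium, 0.598 for G2 and mitosis, 0.338 for G1/S and replication, 0.532 for immediate early and 0.775 for interferon response. For Ly6D+Gfra2+ against Ly6D−Gfra2− it was 0.193 for erythroid and megakaryocyte, 0.836 for mature B and plasma cell, 0.836 for stroma and endothelium, 0.446 for G2 and mitosis, 0.836 for G1/S and replication and 0.293 for interferon response. Of these lists the median, the mean and the test differed in sign for V(D)J recombination, T lineage and Notch, NK and innate lymphoid, mature B and plasma cell and G2 and mitosis in the first comparison, interferon response in the middle one, and G1/S and replication, mature B and plasma cell and stroma and endothelium in the last.

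Over genes, the residuals from group and prefix of the 9 pairs of libraries with the same number in different groups had correlations of -0.069 to 0.038, against -0.078 to 0.078 in the 18 pairs of the same prefix with different numbers. For deviations from the group alone the correlations were -0.049 to 0.14 and -0.026 to 0.132. Each prefix holds only a pair of Ly6D+Gfra2− libraries, whose residuals from group and prefix are equal with opposite sign. Their values with the same and with different numbers mirror each other, so the residuals cannot decide on pairing there. For deviations from the group alone the pairs with the same number did not stand apart as a set. The highest value, 0.14, was that of Ly6D−Gfra2− and Ly6D+Gfra2− replicates 6. Xist, however, fell with the number within prefix T in every group. It was at 11840, 8215 and 6423 CPM in Ly6D−Gfra2− replicates 4, 5 and 6, and at 8168, 5006 and 3100 CPM in Ly6D+Gfra2+. In Ly6D+Gfra2− replicates 5 and 6 it was at 6051 and 4257 CPM. Eif2s3y rose with the number in every group, while Ddx3y, Uty and Kdm5d did not. In prefix T, names with the same number also share a tag across groups. Pairing there stays open, and the main values took no account of it.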
